A study of Homo sapiens with 16 samples.

How the data were processed

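HepG2 cells treated with ALA and untreated cells of the same time were labelled and hybridised together on 2-colour Agilent arrays, with Cy5 for treated and Cy3 for control RNA per the labels. The 16 samples fall into 4 groups of 4 by concentration (2.5 mM, 25 mM) and time (2 h, 24 h). The labels call them biological replicates; nothing more was stated on separate cultures, so p-values measure the spread between these samples. Scanner files read here cover 3 arrays of 2.5 mM at 24 h, 1 of 25 mM at 24 h and 1 of 25 mM at 2 h; other arrays were not analysed here, and no column of per-sample values was left unused.

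The scanner files hold spot brightness as intensity, made with Agilent Feature Extraction 10.7.1.1 per the file headers, which name build hg19. Their log ratio is the log10 of red over green after the software's own background and dye correction, per the file headers. For each group the authors deposited a table with the column names of limma: a log2 fold change, a mean log2 intensity, a moderated t and a log odds as score, and a p-value with its adjusted form. Background correction, normalization and model behind these deposited tables are not given in the sources used here. The deposited log2 mean intensities were equal in all 4 tables, and so were the standard errors (fold change over t, median 0.108), as from 1 joint fit; t and p gave 15.62 degrees of freedom. The deposited adjusted p-value is up to 58341 times the unadjusted one, so the adjustment covered more probes than the 20635 in a table. The median mean intensity was 6.40 (log2), and 4850 rows reached 8, so many rows lie near background.

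Counts from the tables used 1 row per gene name (the smallest p) at an adjusted p under 0.05. Of 20635 rows, 13896 had an accession in the RefSeq name table given (assembly GRCh38.p14, names only); in 1318 the table's gene name differed from it, and those rows were neither named nor put in a list. Differences between tables were divided by the root of the summed squared standard errors, tested two-sided with 15.62 degrees of freedom, and adjusted by Benjamini-Hochberg over the 20635 rows. Gene lists (35, fixed before the data were examined, 371 of 718 members in the tables) were tested with limma's cameraPR on the moderated t with a preset correlation of 0.01, adjusted over the 34 lists with at least 3 members. An estimated correlation per list came from the 3 arrays of 2.5 mM at 24 h with the sign turned, with values under 0 set to 0. It was applied to every table. From 3 arrays it is imprecise, and a shared response that differs in size between arrays raises it. Values set to 0 are looser than the preset 0.01.

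Scanner spots were read with limma 3.58.1 in R 4.3.3. The design named mean signals; the files read here hold medians, so median signals and median backgrounds were used, corrected by normexp with an offset of 50 and normalized by loess within each array with control spots at weight 0. Spots flagged as outliers were left out, spots of a probe averaged, and each gene taken from its brightest probe. Probes were named through their accession: 30532 of 58201 matched 22003 symbols. One limma fit held a mean per group, so that the spread came from the 3 arrays of 2.5 mM at 24 h. No spot was saturated. The 4 arrays of 24 h share a slide and scan and the 2 h array has its own, so slide and time cannot be told apart. The sign turn set each array against the labelled orientation where it correlated negatively with its group's table.

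Named genes followed a rule written before the data were examined. It takes the 8 largest and 8 smallest fold changes past the threshold per comparison, up to 4 members of smallest p per described list, the heme synthesis genes and HMOX1 always, and 5 per direction for differences. Where none passed, it takes the 3 smallest p in each direction, and loci without a symbol were counted but not named. Alternatives were stricter and looser thresholds, the brightest row of a gene, all probes, rank and preset versions of the list test, other background and dye corrections, dim-probe filters and leaving out each array. On simulated data with the spread of the tables, the limma step with 3 arrays recovered 76 of 100 probes changed by 1 (log2) and 99 of 100 changed by 2, with 8 false calls among 20635. With 2 arrays, as when a replicate is left out, it recovered 1 of 100 and 90 of 100 with 10 false calls. The difference step, simulated for the table comparisons, recovered 82 of 100 and 97 of 100 with 8 false calls, and cameraPR 2 of 2 shifted lists with 0 false calls. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.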

Results

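The series measured transcripts in HepG2, a human liver cancer cell line, after exposure to 5-aminolevulinic acid (ALA), the precursor from which cells build porphyrins and heme. Cells received ALA at 2.5 mM or 25 mM and were harvested after 2 h or 24 h, which gave 4 groups of 4 samples described as biological replicates. Each sample was hybridised against untreated cells of the same time on a 2-colour Agilent array. For each group the authors deposited a table of log2 fold changes over 20635 probes and 15168 gene names, and scanner files of 5 arrays were also read here. Those arrays carried 58201 probes, of which 18192 to 19855 lay well above background in the green channel and 21908 to 29209 in the red channel. The number of arrays limits the precision. The tables do not state their sign, so fold changes were read as ALA over control from the design text. With the opposite sign every "higher" below would read "lower". One sample labelled 25 mM at 24 h (replicate 1) is described elsewhere in its labels as 2.5 mM, and it was kept at 25 mM.

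ALA at 2.5 mM for 2 h went with the broadest change: 3136 of 15168 genes passed an adjusted p of 0.05 in the authors' deposited table, 1426 higher and 1710 lower. IGFBP1, a secreted binder of insulin-like growth factors, was highest at a log2 fold change of 5.05 (SE 0.24) in the authors' deposited table, which is 33.2-fold, with a limma adjusted p of 2.29e-09. Next in the authors' deposited table came KLHDC7B at 4.38, GDF15, a stress-induced cytokine, at 4.26 (SE 0.22), and HMOX1, the enzyme that breaks down heme, at 4.17 (SE 0.22). NMRAL2P (3.48), ABCC2, an efflux pump for conjugates (3.47), GPAT3 (3.07) and MANF (2.93) followed in the authors' deposited table. The lowest values in the authors' deposited table were MT1F at -2.75 (SE 0.37), PEG10 at -2.55, KLB at -2.39, FSCN1 at -2.37, MT1M at -2.33, SPTLC3 at -2.20, MT1B at -2.15 and MT1L at -2.09. The MT1 probes can read close relatives, and the brighter of the MT1M rows in the authors' deposited table gave -1.18.

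Genes of the unfolded protein and integrated stress response rose together at 2.5 mM for 2 h. Of 21 measured members, 16 were higher and none lower in the authors' deposited table (16 adjusted over the list alone), with limma's cameraPR giving an adjusted p of 1.85e-22. DNAJB9 (2.71, SE 0.20) and HERPUD1 (2.52, SE 0.16), both linked to protein quality control in the endoplasmic reticulum, were among them in the authors' deposited table, as were TRIB3 (2.02) and CEBPB (1.92). Of the NRF2 targets, 8 of 11 were higher in the authors' deposited table (8 higher and 1 lower adjusted over the list alone), including AKR1B10 (2.62, SE 0.25) and the autophagy receptor SQSTM1 (1.93, SE 0.26), and the list rose with a cameraPR adjusted p of 1.36e-08. The hypoxia response list rose as well, with 8 of 11 higher and 1 lower in the authors' deposited table (10 and 1 adjusted over the list alone, cameraPR adjusted p = 1.24e-14), led after IGFBP1 by ANKRD37 (1.67), ANGPTL4 (1.31) and ADM (1.41). In the cholesterol synthesis list 7 of 14 were higher and 2 lower in the authors' deposited table (the same counts adjusted over the list alone), with a cameraPR adjusted p of 0.00234. The list of autophagy and lysosome genes had 6 of 9 higher and 2 lower in the authors' deposited table (6 and 2 adjusted over the list alone, cameraPR adjusted p = 0.00514), with GABARAPL1 at 1.35. Immediate early genes had 4 of 12 higher and 1 lower in the authors' deposited table (7 and 1 adjusted over the list alone, cameraPR adjusted p = 0.0109), with ZFP36 at 1.25 and IER3 at 1.68. Glycolysis genes had 5 of 12 higher in the authors' deposited table (5 adjusted over the list alone), with HK2 at 2.29 and PDK1 at 1.39, and a cameraPR adjusted p of 0.0101 that became an adjusted p = 0.115 with an estimated correlation.

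Lists that fell at 2.5 mM for 2 h covered heme synthesis, growth and respiration. ALAS1, the rate-limiting enzyme of heme synthesis, fell to -0.91 (SE 0.11, limma adjusted p = 1.98e-05) in the authors' deposited table, and UROD (-0.86), TMEM14C (-0.78) and PPOX (-0.60) fell too. SLC25A38 (-0.17) did not pass in the authors' deposited table. Of 6 measured members 4 were lower in the authors' deposited table (4 adjusted over the list alone, cameraPR adjusted p = 0.00267). Of 15 antioxidant enzymes, 11 were lower and 3 higher in the authors' deposited table (11 and 3 adjusted over the list alone, cameraPR adjusted p = 0.000529), with CAT at -1.66 and SOD1 at -1.16 against PRDX4 at 0.79. DNA replication genes had 12 of 17 lower in the authors' deposited table (12 lower and 1 higher adjusted over the list alone, cameraPR adjusted p = 1.89e-10), among them UNG (-1.65), GINS1 (-1.25) and CHAF1B (-1.18). Cell cycle genes had 11 of 17 lower in the authors' deposited table (13 adjusted over the list alone, cameraPR adjusted p = 4.10e-07), including UBE2C (-1.40) and BIRC5 (-1.09), with an adjusted p = 0.0694 with an estimated correlation. Nuclear genes of oxidative phosphorylation had 11 of 18 lower in the authors' deposited table (13 adjusted over the list alone, cameraPR adjusted p = 2.32e-07), with NDUFB3 at -1.88 and NDUFB10 at -1.26, and an adjusted p = 0.0907 with an estimated correlation. Metallothioneins had 5 of 7 lower in the authors' deposited table (6 adjusted over the list alone, cameraPR adjusted p = 0.000808), with an adjusted p = 0.227 with an estimated correlation. Replication dependent histones (4 of 15 lower, 8 adjusted over the list alone, cameraPR adjusted p = 0.0219) and proteasome genes (6 of 12 lower, 8 adjusted over the list alone, cameraPR adjusted p = 0.0132) also fell in the authors' deposited table. Their values became adjusted p = 0.135 and adjusted p = 0.115 with an estimated correlation. Mitochondrially encoded genes had 4 of 10 higher in the authors' deposited table (7 adjusted over the list alone, cameraPR adjusted p = 0.0124), with MT-CO1 at 1.89 (SE 0.32), and an adjusted p = 0.496 with an estimated correlation. Among 9 noncoding RNAs, mostly nuclear and chosen after the data were seen, MALAT1 (2.24, SE 0.45), NEAT1 (1.80, SE 0.36) and SNHG12 (1.42) were higher and OIP5-AS1 (-0.72) and SNHG14 (-0.56) lower in the authors' deposited table. RMRP, MEG3, TUG1 and SNHG1 did not pass.

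**Figure D1:**
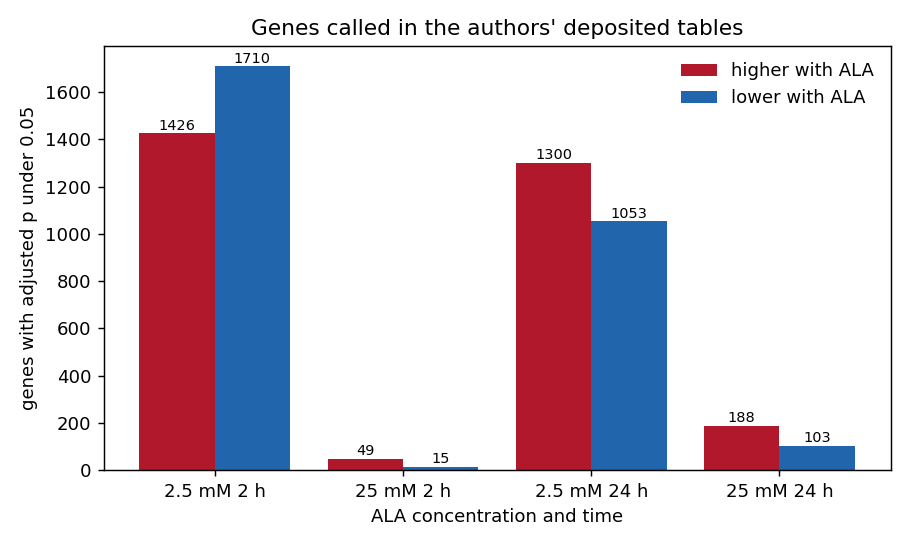
Number of genes (vertical axis) with an adjusted p under 0.05 in each of the authors' deposited tables, by ALA concentration and time (horizontal axis); red bars count genes higher with ALA and blue bars genes lower. The bars run from 1426 higher and 1710 lower at 2.5 mM 2 h down to 49 higher and 15 lower at 25 mM 2 h.

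ALA at 25 mM for 2 h passed the threshold for 64 genes in the authors' deposited table, 49 higher and 15 lower. ATF3, a stress-induced transcription factor, was highest at 1.98 (SE 0.24, limma adjusted p = 0.00168) in the authors' deposited table, followed by GDF15 (1.71), HMOX1 (1.55, SE 0.22), AKR1B10 (1.34), the kinase MAP3K8 (1.23), JUN (1.14), MBNL2 (1.11) and GADD45A (1.09). The lowest named values in the authors' deposited table were CEBPA-DT (-0.84), PRKCQ-AS1 (-0.73), ESPNL (-0.69), XYLT2 (-0.68), PLEKHG3 (-0.67), EXOC3L4 (-0.63), C15orf39 (-0.62) and MSTO1 (-0.59). At an adjusted p of 0.01 the count in the authors' deposited table was 24.

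The p53 target list rose at 25 mM for 2 h, with 3 of 13 members higher in the authors' deposited table (8 adjusted over the list alone, cameraPR adjusted p = 1.09e-20): GADD45A, GDF15 and BBC3 (0.83), the last a promoter of apoptosis. NRF2 targets rose with 2 of 11 higher in the authors' deposited table (5 adjusted over the list alone, cameraPR adjusted p = 3.39e-11), AKR1B10 and ABCC2 (0.81). Among immediate early genes JUN alone of 12 passed in the authors' deposited table (3 higher adjusted over the list alone, cameraPR adjusted p = 2.36e-05). The hypoxia list had 3 of 11 higher in the authors' deposited table, INSIG2 (0.90), ANKRD37 (0.86) and ADM (0.72), with 3 higher and 1 lower adjusted over the list alone and a cameraPR adjusted p of 0.0167. IGFBP1, the leader of that list at the lower concentration, stood at -0.54 (limma adjusted p = 1.00) in the authors' deposited table. Of the unfolded protein and integrated stress response genes, ATF3 was the member past the threshold out of 21 in the authors' deposited table (3 higher adjusted over the list alone, cameraPR adjusted p = 0.00275). The cholesterol synthesis (cameraPR adjusted p = 0.00867), apoptosis (0.0167), and autophagy and lysosome (0.0167) lists shifted upward in the authors' deposited table with no member past the threshold (1, 2 and 1 higher adjusted over the list alone). The last became an adjusted p = 0.0636 with an estimated correlation. Inflammatory genes had CXCL8, a neutrophil chemokine, higher at 0.92 in the authors' deposited table (3 higher and 1 lower adjusted over the list alone, cameraPR adjusted p = 0.00275), with an adjusted p = 0.315 with an estimated correlation. ALAS1 fell to -0.57 (SE 0.11, limma adjusted p = 0.0420) in the authors' deposited table, the single heme synthesis gene of 6 past the threshold (2 lower adjusted over the list alone, cameraPR adjusted p = 0.0167). PPOX (-0.26), SLC25A38 (0.20), UROD (-0.09) and TMEM14C (-0.03) did not pass in the authors' deposited table. Replication dependent histones shifted downward with a median of -0.55 in the authors' deposited table and none of 15 past the threshold (2 lower adjusted over the list alone, cameraPR adjusted p = 6.29e-07). In the rank version of the test 6 of the 11 list shifts at 25 mM for 2 h remained (5 up, 1 down), and those of heme synthesis, unfolded protein and integrated stress response, apoptosis, hypoxia response, and autophagy and lysosome genes did not pass.

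After 24 h at 2.5 mM, 2353 genes passed in the authors' deposited table, 1300 higher and 1053 lower. RMRP, a nuclear and mitochondrial noncoding RNA, was highest at 3.05 (SE 0.60, limma adjusted p = 0.00250) in the authors' deposited table. CD79A (2.74), SLC22A18 (2.39), ANKRD36 (2.39), SLC35E4 (2.38), MT-CO2 (2.36, SE 0.51) and HSCB (2.31) followed in the authors' deposited table. Genes that fell most in the authors' deposited table were GLUD2 (-1.39), ZNF316 (-1.38), ID2 (-1.18), GLRX5, a mitochondrial iron-sulfur cluster protein (-1.17), SH3BGRL (-1.15), EID2 (-1.13), H3F3A (-1.13) and RPL15P20 (-1.13). GLUD2 and RPL15P20 have near-identical relatives that one probe can read.

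All 10 measured mitochondrially encoded genes were higher at 2.5 mM for 24 h in the authors' deposited table (10 adjusted over the list alone), with a median of 2.04 and MT-CO1 at 2.47 (SE 0.32). Their cameraPR adjusted p of 1.43e-07 became an adjusted p = 0.333 with an estimated correlation. Of the same 9 noncoding RNAs, SNHG12 (2.23), NEAT1 (2.13), MALAT1 (1.76), SNHG14 (0.87), TUG1 (0.53) and RMRP were higher in the authors' deposited table, OIP5-AS1 was lower (-0.83), and MEG3 and SNHG1 did not pass. MALAT1, NEAT1, SNHG14 and TUG1 were read from other probes than at 2 h. Among p53 targets 5 of 13 were higher in the authors' deposited table (5 adjusted over the list alone, cameraPR adjusted p = 0.0143), with GDF15 at 2.11, PLK3 at 1.20 and MDM2, the negative regulator of p53, at 0.84. NRF2 targets had 3 of 11 higher in the authors' deposited table (3 adjusted over the list alone, cameraPR adjusted p = 0.00872): ABCC2 (1.99), AKR1B10 (1.51) and ABCC3 (0.90). These values became adjusted p = 0.0562 for p53 targets and adjusted p = 0.0688 for NRF2 targets with an estimated correlation. Nuclear genes of oxidative phosphorylation had 6 of 17 lower and 1 higher in the authors' deposited table (9 and 1 adjusted over the list alone), with SDHC at -0.85 against NDUFV1 at 0.71. Cell cycle genes had 4 of 17 lower (8 adjusted over the list alone), histones 3 of 15 (6 adjusted over the list alone) and proteasome genes 3 of 12 (9 adjusted over the list alone) in the authors' deposited table. All 4 lists gave a cameraPR adjusted p of 0.00702, which became adjusted p = 0.530 for the respiratory and cell cycle lists and adjusted p = 0.127 for histones and proteasome with an estimated correlation. ALAS1 fell to -0.46 (limma adjusted p = 0.0111) and PPOX rose to 0.39 (limma adjusted p = 0.00853) in the authors' deposited table. HMOX1 stood at 0.62 (SE 0.22, limma adjusted p = 0.0981), TMEM14C at -0.45, SLC25A38 at -0.18 and UROD at -0.12 in the authors' deposited table, none past the threshold. The heme synthesis list did not shift (cameraPR adjusted p = 0.711), with 1 higher and 1 lower of 6 in the authors' deposited table. Of 8 leukocyte markers, CD79A and PTPRC (0.89) were higher in the authors' deposited table, while the list did not shift (cameraPR adjusted p = 0.506).

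ALA at 25 mM for 24 h passed the threshold for 291 genes in the authors' deposited table, 188 higher and 103 lower. AKR1B10, an aldo-keto reductase and NRF2 target, was highest at 3.70 (SE 0.25, limma adjusted p = 9.92e-07) in the authors' deposited table. GDF15 (2.61), AKR1C1 (2.25), ATF3 (2.15), HMOX1 (2.14, SE 0.22), IGFBP1 (2.06), the activin antagonist FST (2.05) and AKR1C4 (2.05) followed in the authors' deposited table. FGB, the beta chain of fibrinogen, was lowest at -1.65 (SE 0.23) in the authors' deposited table, followed by AKR1D1 (-1.14), DKK1 (-1.10), DHRS2 (-1.08), CCDC170 (-1.04), MAP2K6 (-1.03), LEAP2 and SORCS2. The AKR1C genes are close relatives that probes may not separate.

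NRF2 targets led the lists at 25 mM for 24 h, with 6 of 11 higher in the authors' deposited table (9 adjusted over the list alone, cameraPR adjusted p = 4.24e-28), including AKR1C3 (1.67), ABCC2 (1.21) and TALDO1 (0.52). Immediate early genes had 5 of 12 higher in the authors' deposited table (9 adjusted over the list alone, cameraPR adjusted p = 9.97e-20): JUN (1.64), FOS (1.44), IER3 (1.24), EGR1 (1.03) and ZFP36 (1.01). Among p53 targets 5 of 13 were higher in the authors' deposited table (8 adjusted over the list alone, cameraPR adjusted p = 2.67e-15), with PLK3 at 0.99 and GADD45A at 0.85. The hypoxia list had 3 of 11 higher and 1 lower in the authors' deposited table (5 and 1 adjusted over the list alone, cameraPR adjusted p = 2.24e-06), IGFBP1, INSIG2 (0.94) and ADM (0.56) against EPO (-0.50). Autophagy and lysosome genes had GABARAPL1 (1.23) and SQSTM1 (1.09) higher out of 9 in the authors' deposited table (2 adjusted over the list alone, cameraPR adjusted p = 0.000111). Heme and porphyrin handling had HMOX1 and the heme transporter SLC48A1 (0.62) higher out of 10 in the authors' deposited table (3 adjusted over the list alone, cameraPR adjusted p = 0.000573, adjusted p = 0.0943 with an estimated correlation). Inflammatory genes had CCL20 (0.92) higher out of 12 in the authors' deposited table (4 adjusted over the list alone, cameraPR adjusted p = 0.000895, adjusted p = 0.256 with an estimated correlation). Proteasome genes shifted upward with none of 12 past the threshold in the authors' deposited table (0 adjusted over the list alone, cameraPR adjusted p = 0.0479, adjusted p = 0.228 with an estimated correlation). ALAS1 fell to -0.78 (SE 0.11, limma adjusted p = 0.000805) in the authors' deposited table, and the heme synthesis list with it (2 of 6 lower adjusted over the list alone, cameraPR adjusted p = 0.000483). PPOX (-0.34), SLC25A38 (-0.19), UROD (-0.13) and TMEM14C (-0.08) did not pass in the authors' deposited table. Of 9 hepatocyte secreted proteins FGB and TF, or transferrin (-0.61), were lower in the authors' deposited table (3 adjusted over the list alone, cameraPR adjusted p = 7.13e-05, adjusted p = 0.277 with an estimated correlation). DNA replication genes shifted downward with none of 17 past the threshold in the authors' deposited table (6 lower adjusted over the list alone, cameraPR adjusted p = 1.77e-05, adjusted p = 0.228 with an estimated correlation).

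**Figure D2:**
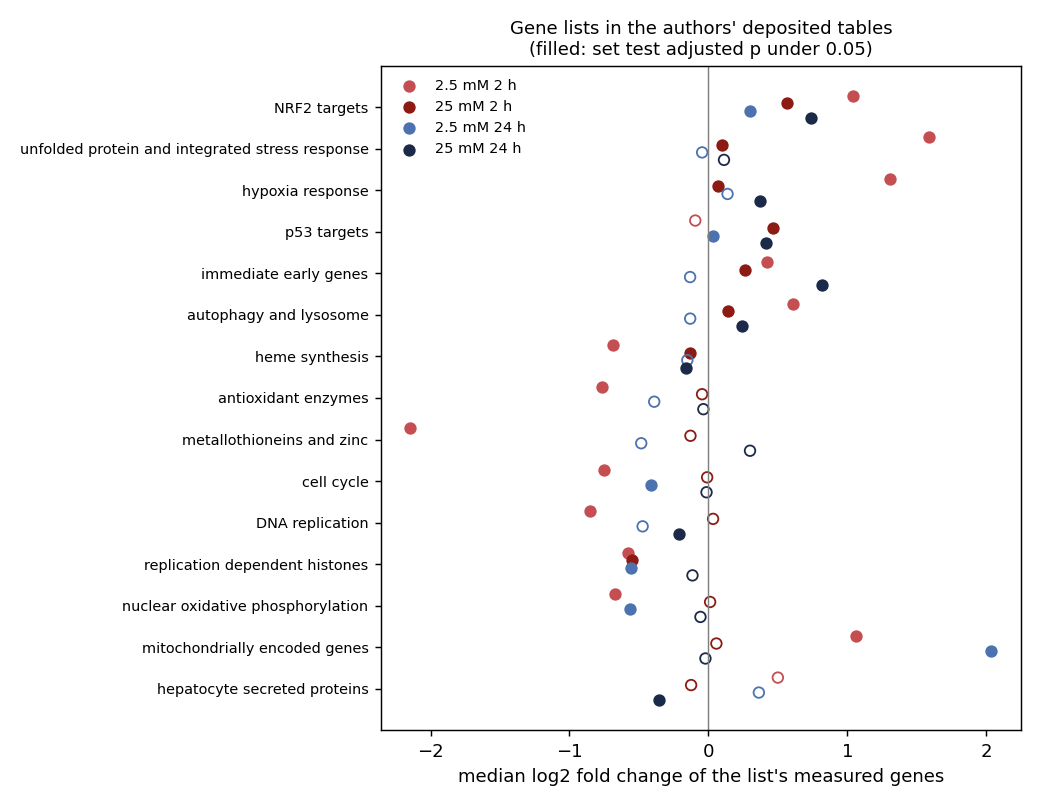
Median log2 fold change (horizontal axis) of the measured genes of 15 gene lists (vertical axis) in the authors' deposited tables, 1 colour per ALA concentration and time; filled points mark a cameraPR adjusted p under 0.05. Mitochondrially encoded genes reach 2.04 at 2.5 mM 24 h, and NRF2 targets are filled in all 4 comparisons. Filling uses the preset correlation, and with an estimated correlation no list call at 2.5 mM 24 h held, these 2 lists included.

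Both concentrations were compared at each time by testing the difference between the authors' fold changes. At 2 h, 1790 genes differed, 795 with the lower value at 25 mM and 995 with the higher, and 97.1% of them had the larger change at 2.5 mM. KLB (0.46 at 25 mM, -2.39 at 2.5 mM), MT1F, PEG10, FSCN1 and SPTLC3 differed most in one direction in the authors' deposited tables. IGFBP1 (-0.54 at 25 mM, 5.05 at 2.5 mM), KLHDC7B, ARHGAP45, GPAT3 and PABPC1L differed most in the other, with differences from -5.59 to -3.03. HMOX1 was lower at 25 mM by a difference of -2.63 (SE 0.32, adjusted p = 4.96e-05 from the authors' limma fold changes). At 24 h, 1433 genes differed, 580 higher and 853 lower at 25 mM, and 84.1% had the larger change at 2.5 mM. AKR1B10, GLP2R, EGR1, FOS and KHDRBS3 were higher at 25 mM, by 2.19, 1.98, 1.95, 1.78 and 1.77. CD79A, SLC35E4, RHBG and CHRD were lower, by differences of -2.65, -2.64, -2.62 and -2.60. The difference for HMOX1 at 24 h was 1.52 (SE 0.32, adjusted p = 0.00617 from the authors' limma fold changes).

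Times were compared in the same way. At 2.5 mM, 917 genes differed, 578 higher and 339 lower at 24 h than at 2 h. EXOC3L4 (2.89), RHBG (2.79), KLB (2.34), SPTLC3 (2.32) and MT1F (2.10) had the largest differences, and KLHDC7B (-4.41), IGFBP1 (-3.81), HMOX1 (-3.55), DNAJB9 (-3.08) and NMRAL2P (-2.85) the smallest. The SPTLC3 rows disagreed in size, at -2.20 and -1.35 at 2 h in the authors' deposited table. At 25 mM, 68 genes differed, 48 higher and 20 lower at 24 h. IGFBP1 (2.60), AKR1B10 (2.36), FST (2.17), AKR1C1 (1.65) and GPAT3 (1.65) were higher at 24 h, and AKR1D1 (-1.57), SORCS2 (-1.39), MAP2K6 (-1.18), ZCCHC2 (-1.17) and CCDC170 (-1.03) lower. The test treats the tables as independent, and it gave 142 genes at 25 mM with summed degrees of freedom.

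Across the authors' deposited tables, 13 genes passed in all 4 comparisons, 8 of them higher throughout and 1, ALAS1, lower throughout. ABCC2, AKR1B10, CLCN6, GADD45A, GDF15, NMRAL2P and PIM1 were named genes among the higher ones; CLCN6 and PIM1 were named after their values were seen. Across probes, which are not independent replicates, the fold changes of 2.5 mM at 2 h and 24 h correlated at r = 0.64 in the authors' deposited tables. The other pairs of the authors' deposited tables gave r = 0.16 between concentrations at 2 h, 0.09 between concentrations at 24 h, 0.25 between times at 25 mM, 0.35 for 2.5 mM 2 h with 25 mM 24 h and -0.03 for 25 mM 2 h with 2.5 mM 24 h. Simulated tables without effects gave 0.50 where they shared their controls and values near 0 where they did not. Per the labels each sample was set against untreated cells of its own time, so different times share no controls. Whether the concentrations of a time shared them is not given in the sources used here. Between times at 2.5 mM the covariance was 0.0947. The simulation with shared controls, which is not the labelled design between times, gave 0.0110. At both times 735 genes were higher (122 for independent lists) and 706 lower (119 for independent lists).

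**Figure D3:**
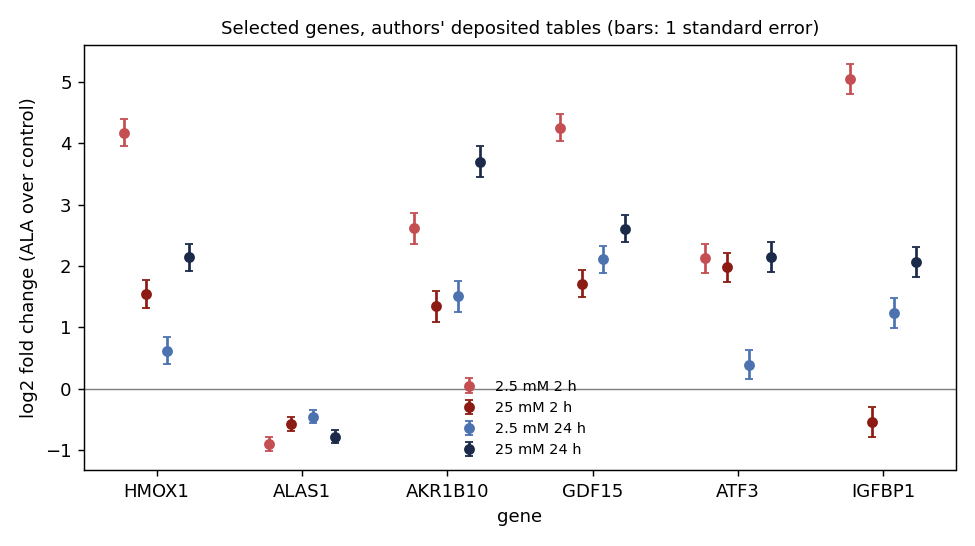
Log2 fold change of ALA over control (vertical axis) for 6 genes (horizontal axis) in the authors' deposited tables, 1 colour per ALA concentration and time; points are the authors' fold changes and bars 1 standard error. HMOX1 runs from 4.17 at 2.5 mM 2 h to 0.62 at 2.5 mM 24 h, and ALAS1 lies under 0 in every comparison.

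As labelled, the 3 arrays of 2.5 mM at 24 h (replicates 1, 2 and 4) do not share 1 direction. The labels place ALA RNA in Cy5 on every array, yet over 58201 probes replicate 1 correlated at r = -0.61 with replicate 2 and with replicate 4, while replicates 2 and 4 correlated at 0.77. With the labelled orientation limma called 0 of 22003 genes (987 at an unadjusted p under 0.05). NOP16 (0.55), SIRPG (0.52), POTEI (0.46), HLX-AS1 (-0.77), C4A (-0.61) and ZNF311 (-0.55) had the smallest p among genes of one sign on all arrays and did not pass (limma adjusted p = 0.835 for each). With the sign of replicates 2 and 4 turned, an alternative chosen after seeing the data, limma called 3654 genes, 2109 higher and 1545 lower. That count was 0 with median centring, 332 without replicate 2, 2720 without replicate 4 and 5327 without replicate 1. Without replicate 1 the turn flips both remaining arrays, so 5327 is also the labelled count and does not check the turn. It was also 0 with the scanner software's processed signals over all probes, and 3889 with those signals over probes well above background in both channels.

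Turned, GDF15 had a mean log2 ratio of 2.41 ± 0.40 (SD, n = 3), IGFBP1 1.65 ± 0.12 (SD, n = 3) and ALAS1 -0.48 ± 0.09 (SD, n = 3). As labelled, the means were -1.11 ± 2.65 for GDF15, -0.57 ± 1.90 for IGFBP1 and 0.23 ± 0.52 for ALAS1 (SD, n = 3). HMOX1 was 0.88 ± 0.88 (SD, n = 3) when turned and 0.14 ± 1.39 (SD, n = 3) as labelled. With median centring the turned means were 0.78 ± 1.08 for GDF15, 0.69 ± 0.90 for IGFBP1 and -0.39 ± 1.96 for HMOX1 (SD, n = 3). The turned mean of ALAS1 was -0.998 ± 0.80 with median centring and -0.98 ± 0.20 with processed signals (SD, n = 3), both lower than with the loess step. With median centring GDF15 was -0.19 on 1 of the arrays. Of 2625 probes called in the authors' deposited table of this group, 2545 (97.0%) had its sign on all 3 arrays when turned and 0 as labelled, though the table includes these arrays and set the turn. The turned mean correlated with the authors' fold changes at r = 0.98 and the labelled mean at -0.84. The authors' values thus run with the turned orientation, not the labelled one. Which RNA each dye held is not settled by that. As labelled, camera shifted 10 lists (8 up, 2 down), led by hepatocyte secreted proteins (median -0.34); turned, it shifted 9 (2 up, 7 down), led by histones (median -0.56). None of either passed with an estimated correlation.

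The single arrays of 25 mM have no replicate check. On the 24 h array (replicate 3), which ran the way of the authors' deposited table of its group, the log2 ratio was 4.21 for AKR1B10, 2.36 for GDF15, 1.90 for HMOX1, 1.86 for ATF3, 1.40 for IGFBP1, -0.32 for ALAS1 and -1.95 for FGB. Turning arrays toward their tables leaves this array as labelled; if treated and control RNA were exchanged on it, each value would take the opposite sign. ALAS1 on it was -0.82 with processed signals and -0.018 with median centring. On the 2 h array (replicate 2) the labelled log2 ratio was -2.64 for GDF15, -2.51 for ATF3, -1.71 for AKR1B10, -1.64 for HMOX1 and 0.38 for ALAS1; turned, GDF15 stood at 2.64, ATF3 at 2.51, AKR1B10 at 1.71, HMOX1 at 1.64 and ALAS1 at -0.38. These values depend on the loess step. As labelled, median centring of the 2 h array gave 0.71 for HMOX1, 0.47 for AKR1B10, -0.025 for GDF15, -0.52 for ATF3 and 1.55 for ALAS1. Median centring subtracts 1 value per array and leaves a trend with brightness in place. On this array it put 10356 probes with a gene symbol at 1 or higher and 74 at -1 or lower. With loess these numbers were 232 and 938. Median-centred values of single genes therefore cannot settle a direction. Called probes in the authors' deposited tables with an unflagged spot on the array were 307 of 308 at 24 h and 66 of 66 at 2 h. Of these, 307 of 307 had the sign of the 24 h array and 0 of 66 that of the 2 h array as labelled. The tables include these arrays, so agreement in size or sign over called probes is partly built in. Over all 20635 probes the arrays correlated with their own tables at r = 0.25 (24 h) and -0.30 (2 h). The 2 arrays correlated at r = -0.59 with each other.

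**Figure D4:**
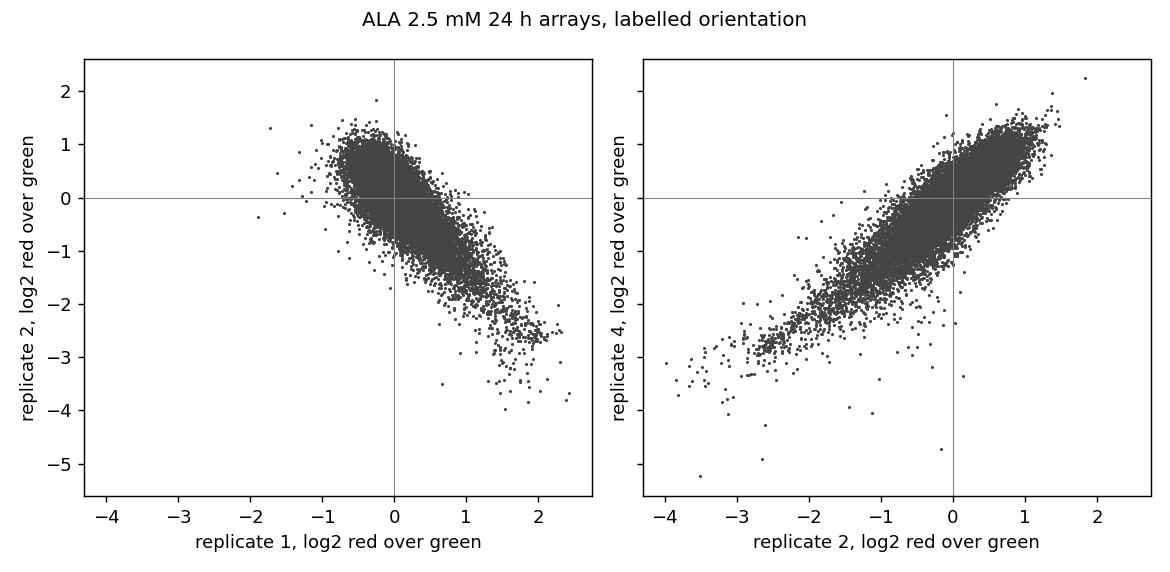
Log2 red over green of the ALA 2.5 mM 24 h arrays in the labelled orientation, 1 point per probe well above background in both channels on all 3 arrays (15997 probes); the left panel sets replicate 1 against replicate 2 and the right panel replicate 2 against replicate 4. The left cloud slopes down (r = -0.81) and the right cloud up (r = 0.89).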

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

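The tests of how doses and times differ were planned; the tests of explanations below were chosen after the results were seen. Fold changes differed between groups by the test of the difference itself for 1790 genes between the concentrations at 2 h, 1433 genes between the concentrations at 24 h, 917 genes between the times at 2.5 mM and 68 genes between the times at 25 mM.

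The lower concentration had the larger changes at both times. Exchanged tables at 24 h are argued against by the scanner files: 4 of the 4 arrays of that time correlated most, in size, with the table of their own group. At 2 h 1 array was read, and its r of -0.298 with its own table was larger in size than with any other, which excludes nothing on its own. Arrays of opposite sign that cancel in the 25 mM fits could also lower the counts there. Over called probes the single 24 h array was 0.807 times the size of the table at the median and the single 2 h array 1.02 times. Cancelling would make them larger, but called probes were chosen by their table values, and probes lost to cancelling are not among them. Over all probes these arrays correlated with their tables at r = 0.25 (24 h) and -0.298 (2 h), against 0.78 to 0.91 in size for the 2.5 mM arrays. The authors' fold changes had an SD over genes of 0.207 (25 mM 24 h) and 0.152 (25 mM 2 h), against 0.383 (2.5 mM 24 h). Smaller changes alone would lower r, so r does not test cancelling. With 1 array per group cancelling stays open. Exchanged cultures before hybridisation and a true effect of concentration were not tested and stay open.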

How the results depend on the processing

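Alternatives with the sign turned, the minimum mean intensity, the name check, the estimated correlation and those with a dye effect or with other signals over brighter probes were chosen after seeing the data. For the deposited tables, an adjusted p under 0.01 gave 24 genes (25 mM 2 h), 1519 (2.5 mM 24 h) and 182 (25 mM 24 h). A log2 fold change of at least 1 gave 786 (2.5 mM 2 h), 10 (25 mM 2 h), 424 (2.5 mM 24 h) and 61 (25 mM 24 h). An unadjusted p under 0.05 gave 878 (25 mM 2 h), 3925 (2.5 mM 24 h) and 1460 (25 mM 24 h), and a mean intensity of at least 8 gave 1904 (2.5 mM 2 h) and 41 (25 mM 2 h), from fewer genes tested. For differences, at least 1 on the log2 scale gave 702 (doses, 2 h), 522 (doses, 24 h), 329 (times, 2.5 mM) and 29 (times, 25 mM); an adjusted p under 0.01 gave 1040, 768, 506 and 29 in that order, and summed degrees of freedom 142 (times, 25 mM). List shifts numbered 9 (2.5 mM 2 h), 0 (2.5 mM 24 h) and 6 (25 mM 24 h) with an estimated correlation and 6 (25 mM 2 h) in the rank version, which also ended the calls of NRF2 and p53 targets at 2.5 mM 24 h and of heme and porphyrin handling at 25 mM 24 h. With the brightest row CASP8 turned to -0.028 at 2.5 mM 2 h and -0.10 at 2.5 mM 24 h and DNM1L to -0.10 at 2.5 mM 2 h, since the rows of these genes disagree. Of 2404 other settings of genes named from the tables, 2064 kept direction and side of the threshold, as did 508 of 544 for lists and 116 of 120 for differences.

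For the scanner files of 2.5 mM at 24 h, the labelled count of 0 became 987 at an unadjusted p under 0.05, 3654 with the sign turned and 3930 with a dye effect besides; leaving out 1 replicate gave 0 to 5327, the highest without replicate 1. The turned count of 3654 became 0 with processed signals or median centring over all probes, with or without a dye effect, and 6816 at an unadjusted p under 0.05. Leaving out 1 replicate gave 332 to 5327, where 5327 is the count without replicate 1 in either orientation. With processed signals 13413 probes (23.0%) had exactly the same ratio on every array, which pulled limma's prior degrees of freedom down to 0.401; over probes above background in both channels there was no such probe, the prior was 6.87 and 3889 genes passed, so that 0 rests on dim probes rather than on the orientation. Median centring over these probes gave 1122, of which 3 were higher and 1119 lower. As labelled, processed signals gave 0 over either set of probes. List shifts became 0 with an estimated correlation in either orientation and 6 with processed signals, and 2 to 11 with 1 replicate left out, the lowest without replicate 4. Turned, leaving out 1 replicate gave 2.25 to 2.64 for GDF15, 1.58 to 1.70 for IGFBP1, 0.56 to 1.39 for HMOX1 and -0.53 to -0.45 for ALAS1, which did not pass without replicate 2 or replicate 4; processed signals and median centring over all probes ended the calls of GDF15, IGFBP1 and ALAS1. Probes with a gene symbol and a log2 ratio of at least 1 in size numbered 1089 (24 h) and 1170 (2 h) on the single arrays. They became 5117 and 6272 with processed signals and 2009 and 10430 with median centring. With median centring 1973 were higher and 36 lower at 24 h, and 10356 higher and 74 lower at 2 h, as labelled. Those splits are 1-sided because median centring leaves a trend with brightness in place. limma with the spread of the other arrays, which assumes that a lone array varies like them, called 0 on each as labelled, and 857 and 824 once arrays were turned toward their tables. Of 298 values of named genes on the single arrays, 242 moved with median centring, 105 with processed signals and 10 without background correction. Apart from that of processed signals, the cause was not tested for any of these. The slide as a block was not run, since the arrays of this group share a slide. No paired analysis was possible because the groups share fewer than 2 replicate numbers among the arrays read. Signal over background limits dim probes.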

Other observations

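The tests of explanations in this part were chosen only after the results were seen. Of 35 lists, 21 shifted in at least 1 of the authors' deposited tables and 13 in none: iron handling, heat shock, DNA repair, mitochondrial biogenesis and dynamics, gluconeogenesis, fatty acid synthesis and oxidation, xenobiotic metabolism, hepatocyte transcription factors, interferon stimulated genes, ribosomal proteins, GABA and glutamate receptors and transport, and the fibroblast and leukocyte markers. With an estimated correlation 12 of the 21 held in at least 1 table, and 9 held in none: metallothioneins, cell cycle, mitochondrially encoded genes, nuclear oxidative phosphorylation, glycolysis, proteasome, inflammatory genes, heme and porphyrin handling, and hepatocyte secreted proteins. The endothelial list had 2 measured members and was not tested. Within lists that did not shift at 2.5 mM for 2 h, iron handling had 5 of 10 members lower in the authors' deposited table, among them PCBP2 (-0.94) and ISCU (-0.90), the latter tied to iron-sulfur cluster assembly, and DNA repair had OGG1 higher at 0.62. BLVRA, which reduces the biliverdin that heme oxygenase makes, was lower there at -1.21 and at -0.70 after 24 h.

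Replicate arrays of 2.5 mM at 24 h ran in opposite directions. Gene-specific dye effects are argued against, since they would make arrays of one orientation alike, and the highest r of replicate 1 with the other 2 was -0.61. With median centring the highest was 0.03 over all probes and -0.55 over probes above background in both channels, where no choice of signals gave a higher value. Red and green exchanged in the files are argued against by the spike-in slopes, the lowest of which was 0.742. A dye swap not named in the labels may be the source: against the table of 2.5 mM at 2 h, which rests on other arrays, the 3 arrays kept their opposite signs with a smallest size of r of 0.494. Of the 5 arrays read, replicate 1 of 2.5 mM at 24 h and replicate 3 of 25 mM at 24 h ran with their own table as labelled. Replicates 2 and 4 of 2.5 mM at 24 h and replicate 2 of 25 mM at 2 h ran against theirs. A dye swap between odd and even replicates would give that pattern, though 5 arrays do not settle it. Exchanged tubes of treated and control RNA would look the same as a dye swap and stay open. Of the 4 sign patterns, the one that set replicate 1 against replicates 2 and 4 gave 3654 genes. The labelled signs gave 0, as did turning replicate 2 or replicate 4 alone. Since no count can lie under 0, the patterns cannot test the labelled count. With 4 patterns a share under 0.05 is also out of reach.

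Mitochondrially encoded RNA was higher at 2.5 mM for 24 h. A dye effect on these probes stays open. After turning the signs the lowest of the 3 array medians was 1.41, but with median centring it was -0.59. Median centring leaves a trend with brightness in place, so its value is a weak check. Over probes above background in both channels it called 3 genes higher and 1119 lower when turned. With the loess step the turned medians of the single 25 mM arrays were 0.86 (24 h) and 1.24 (2 h). The 2 h median was -1.24 as labelled, so its rise rests on the turned sign. In the authors' deposited tables this list did not shift at 25 mM at either time. With 1 array per group, whether the rise is particular to 2.5 mM is not settled. More mitochondria, with nuclear genes of the respiratory chain rising alike, stay open. Those nuclear genes had a median of -0.56, so a rise alike was not seen. Their fall did not pass with an estimated correlation, and RNA levels of nuclear genes do not count mitochondria. RNA composition that differs between extracts stays open. The standard errors of these probes lay at the 95.2th percentile of 4850 bright probes at the median. Standard errors were equal in every deposited table, as from a joint fit. They therefore cannot tell whether the extracts of 2.5 mM at 24 h differed in composition. The noncoding RNAs chosen after the data were seen do not settle whether RNA composition differed. MALAT1, NEAT1, SNHG12, SNHG14, TUG1 and RMRP were higher, OIP5-AS1 was lower, and MEG3 and SNHG1 did not pass. An effect of ALA on mitochondrial RNA itself stays open.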
